A study of Homo sapiens with 48 samples.

How the data were processed

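Total RNA from 48 LNCaP samples, 16 groups of 3 per the labels, was sequenced by the authors, and 12 tables of genes were deposited, each comparing a treated group with its control. Whether the 3 libraries of a group come from separate cultures is not stated, so p values measure only the spread between samples. The labels give no pairing of replicate numbers across groups, and samples were treated as unpaired. The series text names Trim Galore, STAR, HTSeq, edgeR and the hg19 build; their versions and settings are not given in the sources used here. Per the labels RNA was taken up in Trizol and purified with RNeasy columns, the library kit named is one for DNA, and the strand of the reads is not stated, so counts of antisense and overlapping genes are uncertain.

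The read count columns were deposited by the authors as whole numbers per gene and library. Signal columns, the normalised counts, were made by the authors by dividing each count by a size factor set for each table, so levels from different tables are on different scales. FPKM values, deposited by the authors beside the counts, were not used here. The log2 fold changes, per the file headers, compare the first group with the second and were taken as deposited. The p-value columns, with an adjusted p-value beside each, were computed by the authors with settings not given in the sources used here. Of the 12 tables, 11 hold only genes with an adjusted p under 0.05, at coordinates of the GRCh38 build that match GENCODE 29, although the series text names hg19. The day 11 knockdown table holds all 28664 genes with a count, at hg19 coordinates.

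For the day 11 knockdown, genes were kept with edgeR's filterByExpr, libraries were scaled with TMM, and 15436 genes were tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment. For the other 11 comparisons such a test needs the unlisted genes, so the calls, fold changes and adjusted p values are the authors' own. The threshold was an adjusted p under 0.05 in all comparisons. Means and SDs are over the 3 libraries of a group, of the authors' normalised counts except at day 11. For day 11 the counts were divided here by median-of-ratios size factors, which differ from the TMM scaling of the edgeR test. Lists of genes, 22 in all, were written before the data were examined, as were the tests, the thresholds and most alternatives. In each comparison a list with at least 3 called members was tested with Fisher's exact test for its share of higher genes against the other called genes, adjusted over the lists. At day 11 lists were tested with camera from limma over all tested genes, at its preset correlation and at an estimated one. Overlaps between comparisons were counted on genes called in both, with an exact binomial 95% interval for the share in the same direction. Fisher's test and this interval count genes as independent, with no allowance for genes that move together. Such p values may therefore be too small and such intervals too narrow. The number expected of independent lists is the product of both counts over the smaller number of genes tested. For day 11 the 20627 genes with an adjusted p by the authors were taken as tested, not the 15436 of the edgeR test. Expected numbers for day 11 with IBRD9, dBRD9 and CSS medium are therefore lower than 15436 genes would give. For the 11 tables of called genes the number tested is not given. It was inferred here from the p values, their ranks and the adjusted p values of the listed genes. Where both comparisons use the same control libraries, 20 simulated sets of unchanged groups gave the covariance that the shared control makes over all simulated genes. Simulated genes, with their control means and dispersions, were taken from the genes called with JQ1 against that control, and drawn gene by gene. Control shifts common to many genes were therefore not simulated, and the simulated covariance may be too small. The covariances set beside the simulated covariance are over called genes only, so the contrast does not measure the part of the shared control among called genes. Differences between treatments with the same control, and between media, were tested with edgeR on genes listed in both tables, so they say nothing of genes listed in one. The SEs given with edgeR values, also at day 11, were derived here from the log2 change and the F statistic. The 95% intervals of differences use these SEs with a normal quantile, so with 3 libraries per group they may be too narrow. Levels across tables were joined by scaling each table to the DMSO libraries it shares with the table that compares both media. Words of 7 bases were counted in the longest 3' UTR of called coding genes with a mean of at least 100 counts and a UTR of at least 50 bases, and scored by the log2 fold change of genes with and without the word after adjustment for UTR length and GC content, with fold changes limited to 3 in size and, at day 11, the authors' calls; words in fewer than 20 genes were left out.

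Named genes were set by rule. They are BRD9, the 8 genes with the largest positive and the 8 with the largest negative log2 fold change among protein-coding genes past the threshold with a mean of at least 100 normalised counts over the 6 libraries and non-overlapping groups, 2 to 4 members of each list described, and KLK3, KLK2, TMPRSS2, FKBP5 and MYC. Some genes that the rule names are not reported here. A gene named in any comparison may be given in another. Chance alone separates 3 against 3 libraries for 10% of genes.

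Tests were tried on simulated data. With 200 planted changes among 15436 genes edgeR called 97% of those with a log2 change of 1 and 100% of those of 2, with 5.74% false calls, and DESeq2 called 97% and 100% with 3.43%. The difference test recovered 99% of planted differences with 2.94% false calls. That simulation had 1000 genes with the same dispersion, equal library sizes and 200 differences of log2 1, all in the same direction. The real tests used genes called in both tables and unequal libraries, and the test between media was not simulated. These rates may therefore not hold for the differences reported. The direction test of lists passed 4.8% of random lists and 77% of skewed ones. Both kinds were drawn gene by gene, so lists of genes that move together were not tried. The word search ranked 5 of 5 planted words first. Alternatives were an adjusted p under 0.01, a change of at least 2-fold, a mean of at least 100 counts, refits of the listed genes with edgeR and DESeq2, a replicate block, and leaving out each library. R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 was used, and Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.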

Results

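RNA-seq libraries of LNCaP, an androgen-responsive human prostate cancer cell line, were compared after BRD9 was depleted or blocked and after a change of serum or compounds. BRD9 is a bromodomain subunit of the non-canonical BAF chromatin remodelling complex. The 48 libraries form 16 groups of 3. A set of 4 groups holds cells with lentiviral shRNA against BRD9 or a scrambled shRNA, sampled at 11 days of lentivirus or at 3 days of doxycycline induction. For the 11 day groups a treatment field names CRISPR-Cas9 where the labels name shRNA, and the labels are followed here. Another pair holds cells given DMSO or the BRD9 bromodomain inhibitor IBRD9 for 3 days, at 5 µM in the sample labels and at 3 µM in the series text. The other 10 groups spent 24 h in CSS medium, which in this field means charcoal-stripped serum, poor in androgen. Of these, 5 then had compound for 24 h in CSS medium (the CSS groups), and 5 had compound for 6 h in CSS medium and 18 h in regular medium (the regular-medium groups). Their compounds were DMSO, the antiandrogen enzalutamide at 10 µM, IBRD9 at 3 µM, the BRD9 degrader dBRD9 at 500 nM, and the BET bromodomain inhibitor JQ1, at 500 nM in regular medium and at a dose the labels leave out in CSS medium. The table of the day 11 knockdown lists all genes with a count, and its libraries hold 16158513 to 25264783 counts. The other 11 tables list only the genes the authors called, so their sums, such as 13031532 to 16185565 counts per library for 3 days of IBRD9, are parts of a library and the full depth is unknown. A gene not listed there was not called, and its level is not known.

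**Figure D1:**
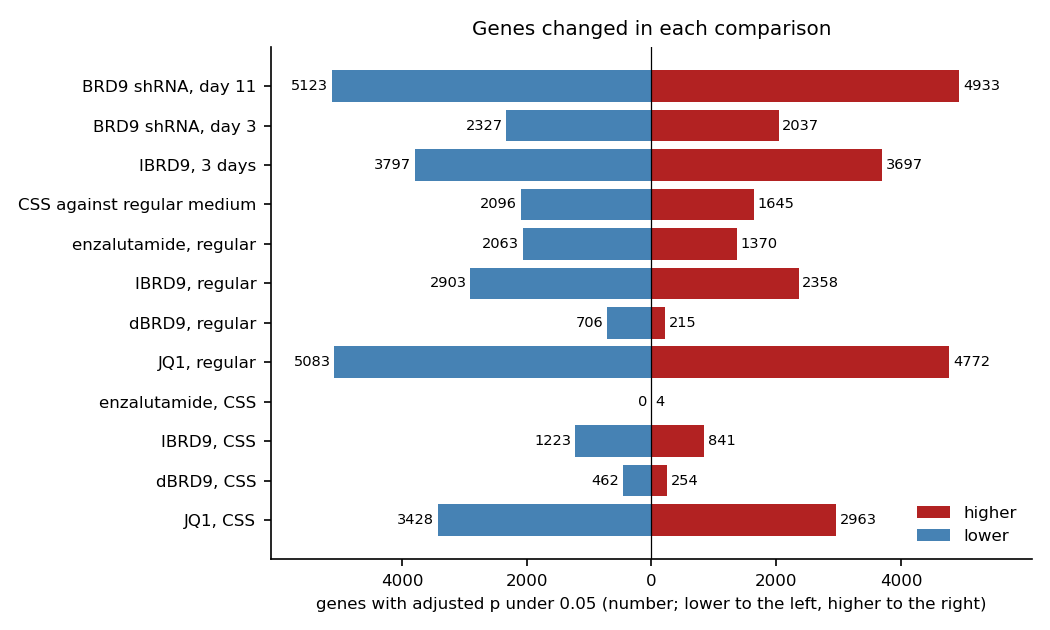
Genes with an adjusted p under 0.05 in each of the 12 comparisons, as numbers of genes, with lower genes to the left and higher genes to the right. The day 11 bar is from the edgeR test and the others count the genes of the authors' deposited tables; JQ1 in regular medium has 5083 lower and 4772 higher genes, enzalutamide in CSS medium has 4 higher genes.

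The first question was what loss of BRD9 does to LNCaP transcripts. After 11 days, BRD9 mRNA was 359 ± 49.4 normalised counts (SD, n = 3) with BRD9 shRNA and 950 ± 34.0 with scrambled shRNA, a log2 change of -1.41 ± 0.09 (SE; chromosome 5, 850406 to 892939, hg19). Genes of cell division were among those that fell. TOP2A, the DNA topoisomerase of dividing cells, changed by a log2 change of -4.11 ± 0.08 (SE), the spindle gene ASPM by -4.24, the replication transcription factor E2F2 by -4.25 and the growth factor midkine, MDK, by -5.08. The fatty acid synthase gene FASN rose, at 165055 ± 6093 normalised counts (SD, n = 3) against 28491 ± 1468, a log2 change of 2.53. The glycoprotein gene GPNMB rose by 4.19, the small heat shock protein gene HSPB8 by 4.08, the secreted phospholipase gene PLA2G2A by 4.05 and NOS3 by 3.52. The thyroid hormone deiodinase gene DIO3 had 332 ± 33.2 normalised counts (SD, n = 3) against 2.15 ± 0.967.

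In the same day 11 comparison, edgeR's quasi-likelihood test called 10056 of 15436 genes at a Benjamini-Hochberg adjusted p under 0.05, 4933 higher and 5123 lower, and 3116 of them changed at least 2-fold. All 30 genes of the list of G1/S and DNA replication fell, as did all 30 of G2/M and mitosis, with RRM2 at -3.64, CDC6 at -3.26, ANLN at -3.78 and CENPF at -3.90. Of the 30 genes of MYC and ribosome biogenesis 26 fell and 2 rose, among them MYC itself at -1.84 and LDHA at -1.36. Set tests with camera gave these 3 lists adjusted p = 6.77e-48, 6.87e-73 and 2.14e-09 with a preset correlation, and 0.0172, 0.0196 and 0.0196 with an estimated correlation. Cholesterol and fatty acid synthesis genes rose for 18 of 27 measured, including SCD (2.14) and SREBF1 (1.55), and fell for 5, with camera adjusted p = 0.000506, or adjusted p = 0.475 with an estimated correlation. Androgen-induced genes went both ways. KLK3, which encodes prostate-specific antigen, rose by 0.92 ± 0.05 (SE) and TMPRSS2 by 0.85, while KLK2 fell by -1.29 and FKBP5 had -0.06 ± 0.06 (edgeR adjusted p = 0.357). Of 44 measured androgen-induced genes 25 rose and 13 fell (camera adjusted p = 0.311, and adjusted p = 0.475 with an estimated correlation). Adjusted over the list alone, the counts of changed genes were 30, 30, 28, 23 and 38 for these 5 lists, the same as over all genes.

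At 3 days of doxycycline the same target was lowered less and the change in transcripts was smaller. BRD9 mRNA was 492 ± 3.36 normalised counts (SD, n = 3) against 877 ± 17.8 in the scrambled control (chromosome 5, 850291 to 892824, GRCh38), a log2 change of -0.84 in the authors' deposited table. Genes that fell furthest in the authors' deposited table were RIPOR2 (-2.76), the RNA-binding protein gene RBM24 (-2.54), S100P (-2.43), DHRS2 (-2.18) and the replication factor C gene RFC3 (-2.18), and those that rose furthest were the microtubule-binding protein gene MAPRE3 (1.83), ANKRD52 (1.52), HFE (1.33) and EGF (1.21). The authors' deposited table lists 4364 genes, 2037 higher and 2327 lower, of 15309 tested, with 427 changed at least 2-fold. Cell division genes fell here too. For G1/S 29 genes were lower and 0 higher, with MCM4 at -0.88 and PCNA at -0.82 in the authors' deposited table, and for G2/M 30 were lower and 0 higher, with CDCA8 at -1.35 and PLK1 at -0.94 there. Fisher's exact test of direction against the other listed genes gave adjusted p = 1.8e-07 for both lists. MYC and ribosome genes were lower for 11 and higher for 1, and so were p53 targets such as SESN1 (-0.75), DDB2 (-0.76) and BBC3 (-0.89 in the authors' deposited table), each with Fisher's exact adjusted p = 0.0288. Integrated stress response and amino acid genes were lower for 16 and higher for 1 (Fisher's exact adjusted p = 0.00254), among them the mitochondrial PEP carboxykinase gene PCK2 (-0.81) and TRIB3 (-0.77) in the authors' deposited table. Cholesterol and fatty acid synthesis genes were higher for 13, FASN by 0.74 and SCD by 0.58 in the authors' deposited table, and lower for 3 (Fisher's exact adjusted p = 0.0303). Androgen-induced genes split into 11 higher and 19 lower (Fisher's exact adjusted p = 0.696): in the authors' deposited table KLK3 was at 0.28, TMPRSS2 at 0.13, FKBP5 at -0.41 and MYC at -0.67.

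Both knockdowns changed the same genes in the same direction in most cases. Of 3717 genes called at 3 and at 11 days 3553 (95.6%, exact 95% interval 94.9 to 96.2) moved the same way, 1675 higher and 1878 lower, where independent lists would share 656 and 779 (Spearman's rho 0.867 across genes, which are not independent replicates). In both knockdowns lower genes carried the 7-base word CTATTCA in their 3' UTRs more often. Its score, adjusted for length and GC content, was the lowest of all 7-base words at 3 days (z = -13.35, 515 genes) and at 11 days (z = -8.70, 751 genes), while it ranked 4978 with IBRD9. Of the called genes with the word 81.3% were lower at 3 days, against 49.0% without it, and at 11 days 66.3% against 49.3%. These shares are not adjusted for UTR length, and with IBRD9 and JQ1 they went the other way, at 30.0% against 52.3% with 5 µM IBRD9, 42.5% against 56.6% with IBRD9 in regular medium and 42.1% against 52.0% with JQ1 there. With dBRD9 in regular medium 54 of 72 genes with the word and 603 of 783 without it were lower. Leaving such genes out, and keeping genes with no annotated 3' UTR, left 3803 genes at 3 days, 1932 higher and 1871 lower, and 9154 at 11 days, 4629 higher and 4525 lower. Among lists called at 3 days, cholesterol synthesis then had 12 higher and 3 lower (Fisher's exact adjusted p = 0.105), and G1/S, G2/M, MYC and ribosome, stress response and p53 genes kept adjusted p values of 9.39e-09, 9.39e-09, 0.0106, 0.000685 and 0.0106 in Fisher's exact test. Androgen-induced genes at 11 days were then higher for 24 and lower for 8 (Fisher's exact adjusted p = 0.0303, against 0.159 with all genes), a removal chosen after the results were seen. The set test with camera, which gave this list adjusted p = 0.311 and 0.475 with all genes, was not rerun without the word genes.

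**Figure D2:**
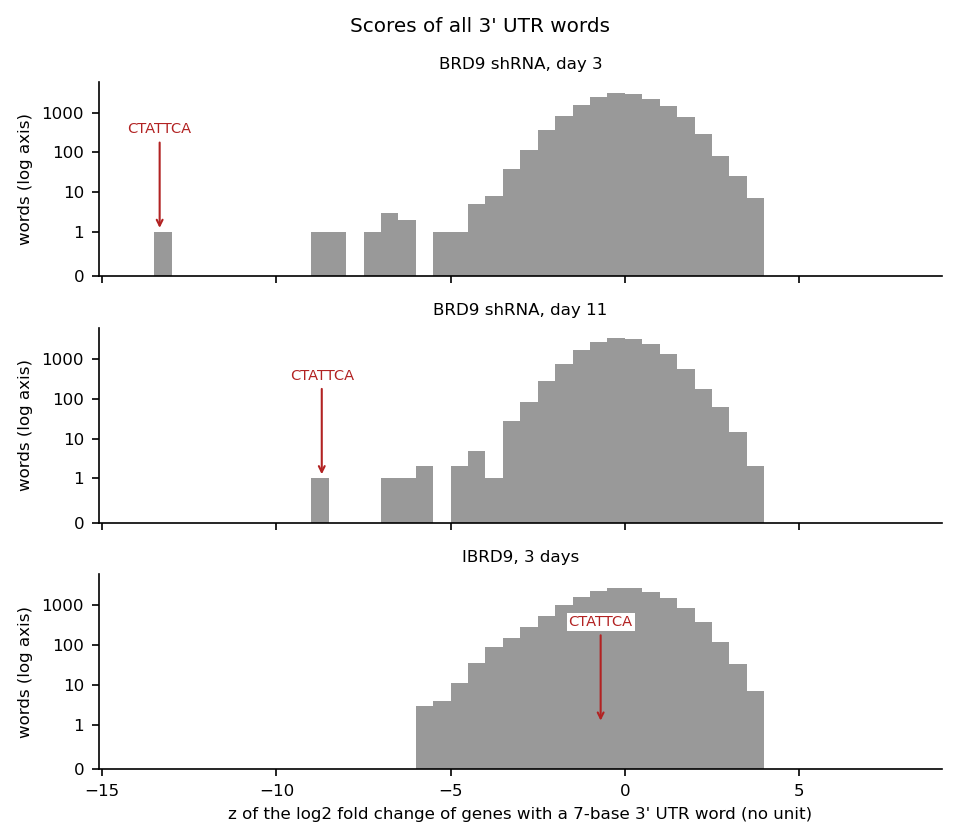
Number of 7-base words (log axis) by the z score of the log2 fold change of genes with each word in the 3' UTR, for called coding genes of 3 comparisons. The word CTATTCA has the lowest score in both knockdowns, -13.35 and -8.70, and lies inside the distribution with IBRD9 at 5 µM, at -0.70.

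Blocking the BRD9 bromodomain with 5 µM IBRD9 for 3 days addressed the same question with a compound. The alpha-tubulin gene TUBA1A rose from 222 ± 7.58 to 3804 ± 295 normalised counts and IGFBP3, an insulin-like growth factor binding protein, from 545 ± 44.5 to 4677 ± 401 (SD, n = 3). KLK2 fell from 10972 ± 218 to 4036 ± 184 and KLK3 from 71858 ± 297 to 45126 ± 1502 (SD, n = 3; chromosome 19, 50861568 to 50880567 and 50854915 to 50860764, GRCh38). The authors' deposited table gives log2 changes of 4.10 for TUBA1A, 3.68 for RCAN2, 3.28 for SHC2 and 2.64 for the secreted protease gene HTRA1, and of -3.74 for the organic cation transporter gene SLC22A2, -3.39 for AMOTL1 and -3.25 for CAMK2N1. TM4SF1 fell from 466 ± 32.7 to 29.1 ± 2.64 normalised counts (SD, n = 3), and BRD9 itself is not listed.

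With IBRD9 for 3 days the authors' deposited table lists 7494 genes, 3697 higher and 3797 lower, of 19928 tested, and 1111 changed at least 2-fold. Every gene of the G1/S and G2/M lists was lower (30 and 30 genes, Fisher's exact adjusted p = 1.99e-08 for each), with MCM2 at -1.41 and UBE2C at -1.37 in the authors' deposited table. MYC and ribosome genes were lower for 25 and higher for 0 (Fisher's exact adjusted p = 4.23e-07), and stress response genes were lower for 18, such as TRIB3 (-1.36) and PCK2 (-1.06 in the authors' deposited table), and higher for 2 (Fisher's exact adjusted p = 0.00212). Genes known to rise under BET inhibitors were higher for 12 and lower for 1 (Fisher's exact adjusted p = 0.00561), including HIST2H2BE (1.34), SAT1 (0.78) and HEXIM1, the inhibitor of the elongation kinase P-TEFb (0.75 in the authors' deposited table). Mitochondrially encoded transcripts were higher for 10 and lower for 0 (Fisher's exact adjusted p = 0.00356), MT-CO2 by 0.31 in the authors' deposited table. Androgen-induced genes were higher for 17 and lower for 18 (Fisher's exact adjusted p = 1): in the authors' deposited table FKBP5 was at -0.41 and MYC at -0.45.

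IBRD9 and the knockdowns shared calls but differed in direction for many genes. Of 2752 genes called with IBRD9 for 3 days and in the day 3 knockdown 1810 (65.8%, exact 95% interval 64.0 to 67.5) moved the same way, 753 higher and 1057 lower, where independent lists would share 492 and 577. With the day 11 knockdown 3332 of 5319 (62.6%, 61.3 to 63.9) did, 1545 higher and 1787 lower against 915 and 976. CAMK2N1, for example, had a log2 change of -3.25 with IBRD9 in the authors' deposited table and of 2.13 at day 11 in the edgeR test, and FASN of -0.39 and 2.53. The degrader dBRD9 in regular medium, described further on and with other control libraries, shared 621 genes with the day 3 knockdown, 552 of them (88.9%, exact 95% interval 86.1 to 91.3) in the same direction, 70 higher and 482 lower against 28.6 and 107 for independent lists. With the day 11 knockdown it was 655 of 771 (85.0%, 82.2 to 87.4), 128 higher and 527 lower against 67.1 and 229. The expected numbers given here for day 11 would be higher with the 15436 genes of the edgeR test.

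The next comparison set CSS medium against regular medium, both with DMSO. The media differ in more than androgen, and the regular-medium cells also had a change of medium, so no effect here is tied to androgen by itself. KLK3 was 584 ± 60.4 normalised counts (SD, n = 3) in CSS medium with DMSO and 31119 ± 451 in regular medium with DMSO, and KLK2 was 43.0 ± 7.35 against 5224 ± 333. In the authors' deposited table KLK2 changed by -6.91 on the log2 scale, the cold-sensing channel gene TRPM8 by -6.16, KLK3 by -5.73, CHRNA2 by -5.45, TMPRSS2 by -3.61 and the co-chaperone gene FKBP5 by -2.38. Genes higher in CSS medium in the authors' deposited table included AMIGO2 (2.78), MID1 (2.76), the myosin kinase gene MYLK (2.59) and the opioid receptor gene OPRK1 (2.31). Of the androgen-induced list 36 genes were lower and 1 higher, and of the androgen-repressed list 6 were higher and 0 lower (Fisher's exact adjusted p = 3.5e-07 and 0.0216), with UGT2B15, which glucuronidates androgens, at 1.86 in the authors' deposited table. UGT2B15 and UGT2B17 are near-identical copies, so their separate counts are uncertain throughout.

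Cell cycle genes were lower in CSS medium too. The authors' deposited table lists 3741 genes, 1645 higher in CSS medium and 2096 lower, of 17796 tested, with 988 changed at least 2-fold. G1/S genes were lower for 30 and G2/M genes for 22, with 0 higher in either (Fisher's exact adjusted p = 3.5e-07 and 1.9e-05), such as UHRF1 (-2.31) and AURKB (-1.34 in the authors' deposited table). Genes of MYC and ribosome biogenesis were lower for 20, of the stress response for 12 and of endoplasmic reticulum chaperones for 8, each with 0 higher (Fisher's exact adjusted p = 4.84e-05, 0.00641 and 0.0284), with NOP56 at -0.81, CHAC1 at -1.53 and HERPUD1 at -0.61 in the authors' deposited table. A refit of the listed genes without regular-medium DMSO library 1, 2 or 3 left 2182, 2204 or 2226 genes, and without CSS DMSO library 1 it left 2143.

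Enzalutamide in regular medium kept androgen-induced transcripts low. KLK3 was 1538 ± 68.3 normalised counts (SD, n = 3) against 29046 ± 480 with DMSO, KLK2 131 ± 11.5 against 4876 ± 318, and TMPRSS2 1405 ± 50.4 against 10435 ± 510. Log2 changes in the authors' deposited table were -5.40 for CHRNA2, -5.34 for TRPM8, -5.23 for KLK2, -4.24 for KLK3, -2.89 for TMPRSS2, -2.21 for FKBP5 and -0.32 for MYC. Higher genes in the authors' deposited table were led by MID1 (2.17), DEGS2 (1.97), SYTL2 (1.91) and MYLK (1.87). The authors' deposited table lists 3433 genes, 1370 higher and 2063 lower, of 14999 tested, with 576 changed at least 2-fold. Androgen-induced genes were lower for 38 and higher for 1 (Fisher's exact adjusted p = 1.19e-06), and androgen-repressed genes higher for 7 and lower for 0 (0.00479 in the same exact test), with UGT2B15 at 1.55 and OPRK1 at 1.75 in the authors' deposited table. G1/S and G2/M genes were lower for 30 and 29 with 0 higher (Fisher's exact adjusted p = 3.26e-06 and 4.11e-06), MYC and ribosome genes for 20, stress response genes for 15 and chaperones for 10, each with 0 higher (0.000184, 0.00265 and 0.0198 in the same exact test), for example CDC6 (-2.12), CDK1 (-1.06) and CHAC1 (-1.59 in the authors' deposited table). Cholesterol and fatty acid synthesis genes were lower for 16 and higher for 2 (Fisher's exact adjusted p = 0.031).

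Genes moved by enzalutamide were largely those moved by CSS medium. Of 2525 genes listed for both, 2520 (99.8%, exact 95% interval 99.5 to 99.9) went the same way, 961 higher and 1559 lower against 150 and 288 for independent lists. The covariance of fold changes was 0.981 over these genes. Simulated unchanged groups sharing the regular-medium DMSO libraries gave 0.00939 and 66.5% same-sign values over all simulated genes, with 0 genes called in both. Among simulated genes with an unadjusted edgeR p under 0.05 in both, a mean of 92.95 per set, 100% had the same sign. A high share in the same direction alone therefore does not exclude the shared control. A test of the difference with edgeR on genes in both tables called 142, 76 of them higher with enzalutamide (48 of 151 with TMM scaling), and in 126 CSS medium was further from the control. KLK3 was higher with enzalutamide than in CSS medium, with a 95% interval of 1.32 to 1.67 on the log2 scale (edgeR adjusted p = 3.46e-06). KLK2 and TMPRSS2 were higher by 1.69 ± 0.14 and 0.72 ± 0.08 (SE; edgeR adjusted p = 4.98e-05 and 0.000627). FKBP5 differed by 0.16, with a 95% interval of -0.06 to 0.39 (edgeR adjusted p = 0.424).

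IBRD9 at 3 µM in regular medium lowered DNA replication genes. RRM2, a subunit of the enzyme that makes deoxyribonucleotides, fell from 1747 ± 181 to 149 ± 14.1 normalised counts (SD, n = 3), and KLK3 from 29046 ± 410 to 13611 ± 876. Log2 changes in the authors' deposited table were -4.01 for E2F2, -3.72 for EXO1, -3.62 for DTL, -3.55 for RRM2, -1.47 for KLK2, -1.09 for KLK3, -0.96 for FKBP5, -0.46 for TMPRSS2 and -0.43 for MYC. DPYSL3 (2.34), RCAN2 (1.83), SHC2 (1.72), HTRA1 (1.59) and IGFBP3 (1.54) rose in the authors' deposited table. It lists 5261 genes, 2358 higher and 2903 lower, of an inferred 16979 tested, with 926 changed at least 2-fold. G1/S and G2/M genes were lower for 30 and 29 with 0 higher (Fisher's exact adjusted p = 3.31e-07 for both), androgen-induced genes lower for 29 and higher for 4 (0.000299 in the same exact test), and stress response genes lower for 18 with 0 higher (0.00017). MYC and ribosome genes were lower for 21 with 0 higher (Fisher's exact adjusted p = 3.26e-05). Genes known to rise under BET inhibitors were higher for 8 and lower for 1 (Fisher's exact adjusted p = 0.045), with HEXIM1 at 1.03 and HIST2H2BE at 0.95 in the authors' deposited table. Of 4046 genes also called with 5 µM IBRD9 for 3 days 3969 (98.1%, exact 95% interval 97.6 to 98.5) moved the same way, 1793 higher and 2176 lower against 513 and 649 for independent lists. Of 2318 genes shared with enzalutamide 2130 (91.9%, 90.7 to 93.0) did, 637 higher and 1493 lower against 215 and 399, with a covariance of 0.528 against the simulated 0.00939.

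The degrader dBRD9 at 500 nM changed fewer genes, and most of them fell. KLK2 was 755 ± 81.9 normalised counts (SD, n = 3) against 4692 ± 306 with DMSO, KLK3 9615 ± 852 against 27951 ± 462, and UGT2B15 315 ± 20.3 against 1130 ± 66.3, while the lysosomal cholesterol transporter gene NPC1 rose from 1550 ± 51.1 to 3797 ± 632. Log2 changes in the authors' deposited table were -2.64 for KLK2, -2.14 for DOPA decarboxylase, DDC, -1.84 for UGT2B15, -1.79 for RRM2 and -1.54 for KLK3, and 1.29 for NPC1, 1.24 for ESPN, 1.08 for TLL2 and 1.02 for ZNF692. BRD9, TMPRSS2, FKBP5 and MYC are not listed. The authors' deposited table lists 921 genes, 215 higher and 706 lower, of 15806 tested, with 252 changed at least 2-fold. G1/S genes were lower for 30 and G2/M genes for 29, each with 0 higher (Fisher's exact adjusted p = 0.00261 for both), with CDC6 at -1.33, CCNA2 at -1.41 and TOP2A at -1.29 in the authors' deposited table. Genes known to rise under BET inhibitors were higher for 4 and lower for 0 (Fisher's exact adjusted p = 0.00872), among them HIST2H2BE (0.63) and BRD2 (0.29 in the authors' deposited table). Androgen-induced genes were lower for 6 and higher for 1, androgen-repressed genes lower for 5, stress response genes lower for 14 and chaperones lower for 8 (Fisher's exact adjusted p = 1, 0.707, 0.111 and 0.377). A refit of the listed genes without regular-medium DMSO library 1, 2 or 3 left 518, 575 or 533 genes, and without dBRD9 library 3 it left 560.

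dBRD9 and IBRD9, both directed at BRD9 but given at different doses, were compared on 739 genes in both tables. Of these 698 (94.5%, exact 95% interval 92.5 to 96.0) moved the same way, 95 higher and 603 lower against 32.1 and 130 for independent lists, with a covariance of 0.56 against the simulated 0.00939. The difference test with edgeR called 450 genes, 378 of them higher with dBRD9 (217 of 415 with TMM scaling). IBRD9 was further from the control in 370 and dBRD9 in 39 (277 and 97 with TMM scaling). CDC6, UHRF1 and RRM2 were higher with dBRD9 by 2.01 ± 0.08, 1.99 ± 0.08 and 1.76 ± 0.11 on the log2 scale (SE; edgeR adjusted p = 4.47e-10, 4.47e-10 and 1.08e-08). KLK2, UGT2B15, DDC and KLK3 went further with dBRD9, by -1.16 ± 0.09, -1.19 ± 0.08, -1.83 ± 0.10 and -0.45 ± 0.07 (SE; edgeR adjusted p = 5.72e-08, 2.64e-08, 3.6e-09 and 0.000112). Between enzalutamide and dBRD9 608 of 698 shared genes (87.1%, 84.4 to 89.5) went the same way, 89 higher and 519 lower against 19.6 and 97.1 for independent lists, with a covariance of 0.334 against the same simulated 0.00939. edgeR called 275 of these 698 as differing, 110 higher with enzalutamide (137 of 262 with TMM scaling). RRM2 differed there by 0.04 with a 95% interval of -0.16 to 0.24, while UGT2B15, at 1.55 with enzalutamide and -1.84 with dBRD9 in the authors' deposited tables, differed by 3.39 ± 0.09 (SE; edgeR adjusted p = 2.43e-13). The control libraries, 3 per medium, were too few to split, so part of each excess over independent lists may come from shared controls.

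JQ1 in regular medium changed more genes than the other compounds there. KLK3 fell from 27880 ± 416 to 1032 ± 83.1 normalised counts (SD, n = 3), MYC from 3193 ± 91.4 to 832 ± 99.6 and UGT2B15 from 1127 ± 67.1 to 19.7 ± 4.93, and HEXIM1 rose from 1474 ± 94.2 to 10690 ± 586. AMOTL1, which encodes an angiomotin-like junction protein, went from 273 ± 9.16 to 0.383 ± 0.664. Log2 changes in the authors' deposited table were -6.32 for E2F2, -6.13 for the tyrosine catabolism gene HGD, -5.92 for UHRF1, -5.84 for UGT2B15, -5.36 for KLK2, -4.75 for KLK3, -1.94 for MYC, -1.89 for TMPRSS2 and -1.09 for FKBP5. Higher genes in the authors' deposited table included DPYSL3 (3.60), the kinase gene FYN (3.33), HEXIM1 (2.86), HIST2H2BE (2.39), and BRD9 (0.30). It lists 9855 genes, 4772 higher and 5083 lower, of an inferred 21924 tested, with 3601 changed at least 2-fold. Genes known to rise under BET inhibitors were higher for 12 and lower for 1 (Fisher's exact adjusted p = 0.00479). G1/S genes were lower for 30 and G2/M genes for 27, with 0 higher (Fisher's exact adjusted p = 5.48e-08 and 2.07e-07), and MYC and ribosome genes lower for 27 and higher for 2 (1.45e-05 in the same exact test). Androgen-induced genes were lower for 28 and higher for 7, and androgen-repressed genes lower for 8 and higher for 0 (Fisher's exact adjusted p = 0.00407 and 0.024). Mitochondrially encoded transcripts were higher for 10 and lower for 0 (0.0037 in the same exact test), MT-ND6 by 0.37 in the authors' deposited table.

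Most genes called with both IBRD9 and JQ1 in regular medium moved together. Of 4396 such genes 4176 (exact 95% interval 94.3% to 95.6%) went the same way, 1835 higher and 2341 lower against 663 and 869 for independent lists, with a covariance of 1.15 against the simulated 0.00939. With the 5 µM IBRD9 experiment, which has its own DMSO libraries, the share was 4972 of 5580 (89.1%, 88.3 to 89.9). The difference test with edgeR called 2878 of the 4396 genes, 1374 of them higher with IBRD9 (1451 of 2876 with TMM scaling), and JQ1 was further from the control in 2423. KLK3 and MYC were higher with IBRD9 by 3.66 ± 0.07 and 1.51 ± 0.08 on the log2 scale (SE; edgeR adjusted p = 1.55e-22 and 1.43e-14), and HEXIM1 was lower by -1.82 ± 0.07 (edgeR adjusted p = 2.65e-17). RRM2 differed by 0.26, with a 95% interval of 0.01 to 0.51 (edgeR adjusted p = 0.0809). dBRD9 and JQ1 shared 813 genes, 722 of them (88.8%, 86.4 to 90.9) in the same direction, 120 higher and 602 lower against 64.9 and 227 for independent lists, with a covariance of 0.876 against the simulated 0.00939. edgeR called 622 of these as differing, 478 higher with dBRD9 (318 of 593 with TMM scaling). Enzalutamide and JQ1 shared 2707 genes and 2141 (79.1%, 77.5 to 80.6) went the same way, 709 higher and 1432 lower against 436 and 699, with a covariance of 0.593 against the same simulated value.

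Enzalutamide added in CSS medium raised KLK3 and KLK2. KLK3 was 1370 ± 46.4 normalised counts (SD, n = 3) against 566 ± 58.7 with DMSO, and KLK2 110.0 ± 4.45 against 41.7 ± 7.10. The log2 changes in the authors' deposited table were 1.27 and 1.39. The authors' deposited table lists 4 genes, 4 higher and 0 lower, of 27447 tested, a number inferred from these 4 genes alone. Androgen-induced genes were higher for 3 and lower for 0, with 42 of 45 not listed. Fisher's exact test of direction (adjusted p = 1) cannot judge this list, because all 4 listed genes were higher. A further gene is the signal recognition particle RNA RN7SL2, named after its values were seen. On a scale joined across separately normalised tables through their DMSO libraries, with no test across tables, KLK3 was 1414 ± 47.9 with enzalutamide in CSS medium and 1648 ± 73.2 with enzalutamide in regular medium (SD, n = 3), and KLK2 was 114 ± 4.59 and 140 ± 12.3.

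**Figure D3:**
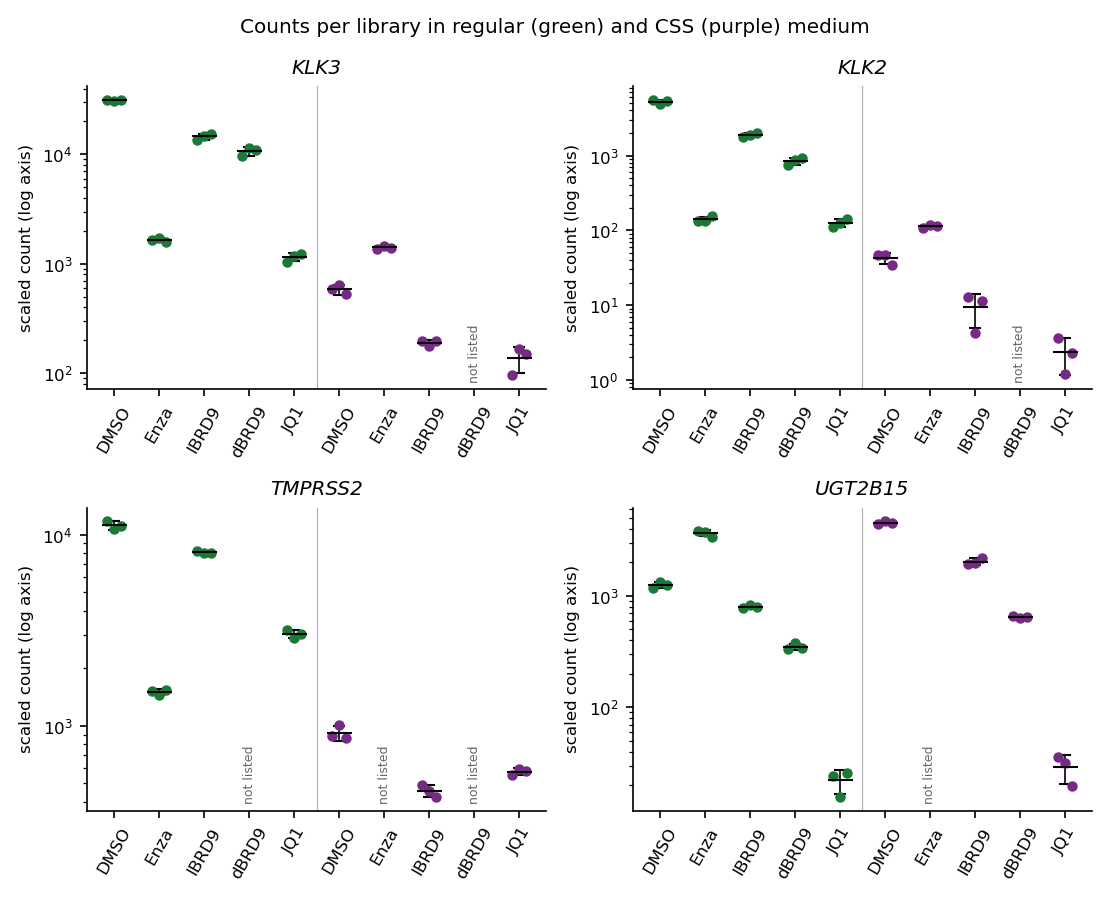
Counts of 4 genes per library (points; n = 3 per group) with mean and SD (bars), on a log axis, in regular (green) and CSS (purple) medium, scaled across separately normalised tables through their DMSO libraries. KLK3 is 31119 with DMSO in regular medium, 584 with DMSO in CSS medium and 1414 with enzalutamide in CSS medium; groups with no point are not listed in the authors' deposited table.

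In CSS medium IBRD9 lowered KLK3 and KLK2 further. KLK3 fell from 567 ± 58.0 to 185 ± 10.4 normalised counts (SD, n = 3), a log2 change of -1.62 in the authors' deposited table. KLK2 fell from 41.8 ± 7.03 to 9.24 ± 4.49 normalised counts. The neuronal pentraxin gene NPTX2 (2.22), DPYSL3 (2.05), UPP1 (1.61) and vimentin, VIM (1.60), rose, and FAM111B (-2.98), DTL (-2.83), COL5A2 (-2.73) and RRM2 (-2.65) fell in the authors' deposited table. It lists 2064 genes, 841 higher and 1223 lower, of an inferred 16104 tested, with 594 changed at least 2-fold. G1/S genes were lower for 25 and G2/M genes for 24, each with 0 higher (Fisher's exact adjusted p = 5.56e-05 for both). Androgen-induced genes were lower for 14 and higher for 2, and BET-response genes higher for 7 and lower for 1 (Fisher's exact adjusted p = 0.101 and 0.0601). An edgeR refit of the listed genes called 1369. A refit without CSS DMSO library 1 left 499 genes, and without IBRD9 library 1, 2 or 3 it left 451, 614 or 528.

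dBRD9 in CSS medium lowered UGT2B15 and UGT2B17, whose enzymes glucuronidate androgens. UGT2B15 fell from 4359 ± 136 to 619 ± 8.36 normalised counts (SD, n = 3) and UGT2B17 from 4923 ± 218 to 955 ± 75.4, and CYP1A2 rose from 33.0 ± 6.01 to 188 ± 26.2. Log2 changes in the authors' deposited table were -2.81 for UGT2B15, -2.50 for ACTRT3, -2.37 for UGT2B17 and -2.13 for DDC, and 2.50 for CYP1A2, 1.52 for NPC1 and 1.34 for ZNF692. KLK3, KLK2, TMPRSS2, FKBP5, MYC and BRD9 are not listed. The authors' deposited table lists 716 genes, 254 higher and 462 lower, of 15582 tested, with 187 changed at least 2-fold. G1/S genes were lower for 24 and G2/M genes for 22, with 0 higher (Fisher's exact adjusted p = 0.00023 and 0.000399), with RRM2 at -1.73 and TOP2A at -1.32 in the authors' deposited table. Chaperones were lower for 8 and higher for 0, HSPA5 by -0.67 in the authors' deposited table (Fisher's exact adjusted p = 0.13). A refit of the listed genes without CSS DMSO library 1 left 123 genes, and without dBRD9 library 1, 2 or 3 it left 106, 145 or 110.

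JQ1 in CSS medium raised NPTX2 and HEXIM1 and lowered androgen-repressed genes. UGT2B15 fell from 4289 ± 131 to 27.1 ± 7.79 normalised counts (SD, n = 3), NPTX2 rose from 44.5 ± 5.85 to 623 ± 41.2 and HEXIM1 from 1856 ± 128 to 11335 ± 561. Log2 changes in the authors' deposited table were 4.93 for CEND1, 3.81 for NPTX2, 3.48 for CADM2, 3.05 for the neuronal microtubule gene MAP2 and 3.05 for synaptophysin, SYP, and -7.31 for UGT2B15, -5.71 for CD274 and -5.70 for IL1RN. KLK3 was at -2.09, MYC at -0.95, TMPRSS2 at -0.67, FKBP5 at 0.59 and BRD9 at 0.39 in the authors' deposited table. It lists 6391 genes, 2963 higher and 3428 lower, of an inferred 20688 tested, with 2939 changed at least 2-fold. BET-response genes were higher for 11 and lower for 0, and androgen-repressed genes lower for 9 and higher for 0 (Fisher's exact adjusted p = 0.00211 and 0.0232). G1/S genes were lower for 22 and higher for 1, G2/M genes lower for 13 and higher for 0 (Fisher's exact adjusted p = 0.000392 and 0.00231), and androgen-induced genes lower for 18 and higher for 9 (0.379 in the same exact test).

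Among the CSS groups dBRD9 and IBRD9 shared 441 genes, 412 of them (93.4%, exact 95% interval 90.7 to 95.6) in the same direction, 76 higher and 336 lower against 13.7 and 36.3 for independent lists, with a covariance of 0.88 against a simulated 0.0227. edgeR called 144 as differing, 117 higher with dBRD9 (90 of 141 with TMM scaling). UGT2B15 went further with dBRD9 by -1.65 ± 0.08 and RRM2 was higher by 0.93 ± 0.13 (SE; edgeR adjusted p = 1.02e-08 and 4.85e-05), and TOP2A differed by -0.07 with a 95% interval of -0.35 to 0.20. IBRD9 and JQ1, whose CSS dose is not given, shared 1419 genes, 1385 of them (97.6%, 96.7 to 98.3) in the same direction, 541 higher and 844 lower against 155 and 260, with a covariance of 2.09 against 0.0227. edgeR called 757 of these, 426 higher with IBRD9, and JQ1 was further from the control in 674. dBRD9 and JQ1 shared 524 genes, 425 (81.1%, 77.5 to 84.4) in the same direction, 109 higher and 316 lower against 48.3 and 102, with a covariance of 1.38 against 0.0227, and edgeR called 343, 237 of them higher with dBRD9 (190 of 426 with TMM scaling).

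The same compound moved genes alike in both media where both tables list them. All 394 genes listed for dBRD9 in both media (100%, exact 95% interval 99.1 to 100) went the same way, as did 1355 of 1377 for IBRD9 (98.4%, 97.6 to 99.0) and 5190 of 5245 for JQ1 (99.0%, 98.6 to 99.2). Independent lists would share 3.50 higher and 20.9 lower genes for dBRD9, 123 and 220 for IBRD9, and 683 and 842 for JQ1, where 82 and 312, 557 and 798, and 2523 and 2667 were found. A test of the difference between media with edgeR called 10 genes for dBRD9, 6 with the higher change in regular medium (13 of 15 with TMM scaling), 285 for IBRD9, 109 higher (148 of 305), and 705 for JQ1, 313 higher. UGT2B17 and UGT2B15 fell less in regular medium with dBRD9, by 1.09 ± 0.11 and 0.97 ± 0.10 (SE; edgeR adjusted p = 2.84e-05 for both). With IBRD9, KLK3 fell less in regular medium by 0.53 ± 0.12 and RRM2 further by -0.90 ± 0.16 (SE; edgeR adjusted p = 0.00538 and 0.000949). The JQ1 dose in CSS medium is not given, so differences between media with JQ1 cannot be told apart from a difference of dose. With JQ1, KLK3 fell further in regular medium by -2.67 ± 0.19 (SE, edgeR adjusted p = 1.12e-06). FKBP5 was at -1.09 in regular medium and 0.59 in CSS medium in the authors' deposited tables, a difference of -1.68 ± 0.17 (SE, edgeR adjusted p = 2.14e-05). HEXIM1 differed with JQ1 by 0.25, with a 95% interval of 0.04 to 0.46 (edgeR adjusted p = 0.154).

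**Figure D4:**
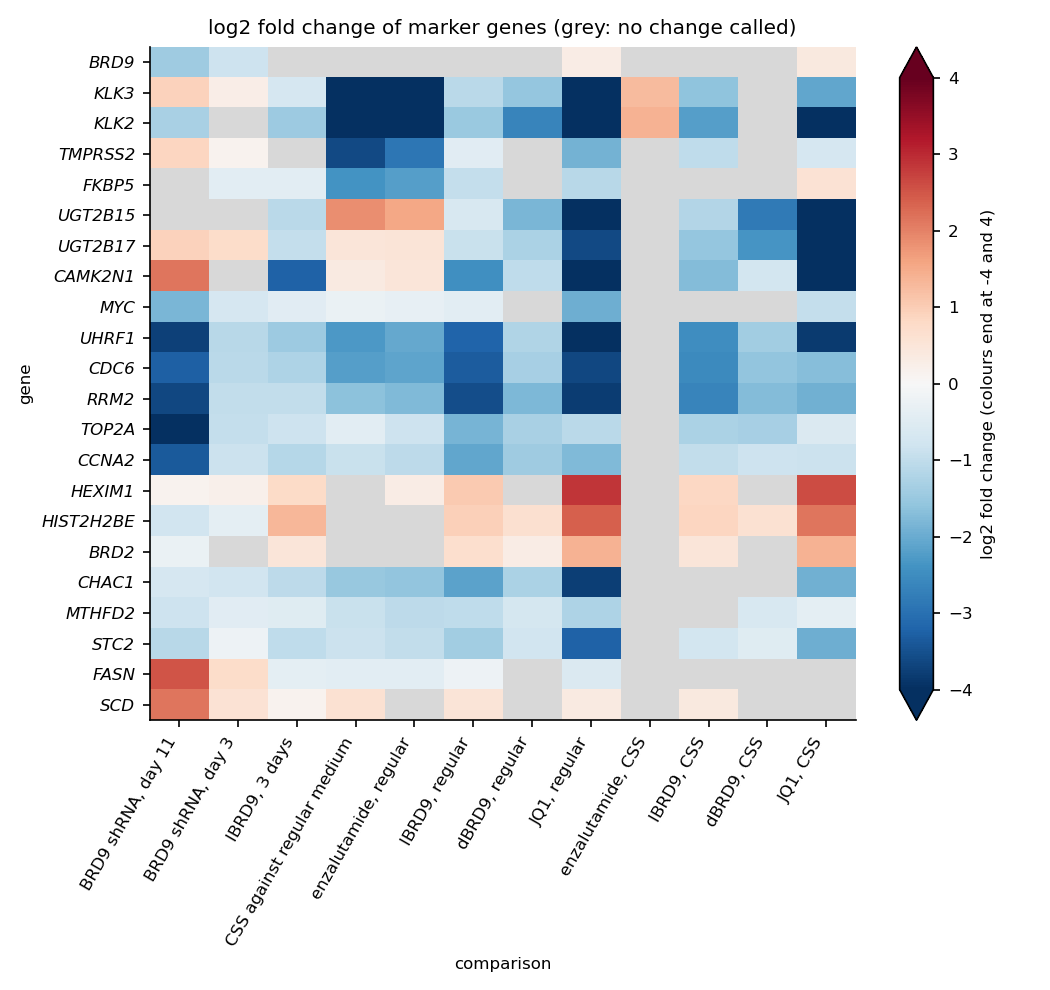
Log2 fold change (colour) of 22 genes in the 12 comparisons, grey where no change was called, from the authors' deposited tables and, for day 11, the edgeR test. KLK3 is at -5.73 in CSS against regular medium, at -4.24 with enzalutamide and at 0.92 with BRD9 shRNA at day 11.

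Changes shared between BRD9 perturbation and either enzalutamide or CSS medium were compared last. Of 1557 genes called with enzalutamide in regular medium and in the day 3 knockdown 1139 (73.2%, exact 95% interval 70.9 to 75.3) moved the same way, 312 higher and 827 lower against 186 and 320 for independent lists. Enzalutamide and 5 µM IBRD9 for 3 days shared 2443 genes, 2123 (86.9%, 85.5 to 88.2) in the same direction, 733 higher and 1390 lower against 338 and 522. CSS medium and regular-medium IBRD9 shared 2419 genes with 2224 (91.9%, 90.8 to 93.0) alike, 768 higher and 1456 lower against 228 and 358, and CSS medium and dBRD9 shared 669 with 567 (84.8%, 81.8 to 87.4) alike, 85 higher and 482 lower against 22.4 and 93.6. Covariances were 0.706 and 0.337 for the last pair of comparisons, against the simulated 0.00939. With DMSO libraries of its own, 5 µM IBRD9 for 3 days shared 2540 genes with CSS medium. Of these 2229 (87.8%, 86.4 to 89.0) were alike, 861 higher and 1368 lower against 342 and 447. The knockdowns, also with control libraries of their own, had lower shares with CSS medium. At day 3 it was 1005 of 1490 (67.4%, 65.004 to 69.8), 254 higher and 751 lower against 219 and 319. At day 11 it was 1653 of 2670 (61.9%, 60.04 to 63.8), 589 higher and 1064 lower against 456 and 603. These day 11 expected numbers would be higher with the 15436 genes of the edgeR test. Cell cycle genes such as CDC6, RRM2 and UHRF1 were lower in all of these treatments and in both knockdowns, while KLK3 was lower in the treatments and higher in both knockdowns, by 0.28 at day 3 in the authors' deposited table and by 0.92 at day 11. UGT2B15 was higher with enzalutamide and in CSS medium and lower with IBRD9 and dBRD9.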

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

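The test for RNA of DMSO cells in regular medium and the counts without the 3' UTR word were chosen after the results were seen. Groups of 3 were not tested for outlying samples, but pairs of libraries were compared by a chi-square per degree of freedom over listed genes. In the table of both media it was 17.03, 13.3 and 46.8 for CSS DMSO pairs 1-2, 1-3 and 2-3. For the regular-medium DMSO pairs it was 5.62, 3.92 and 2.24. CSS DMSO pair 2-3 was also the furthest apart of these control pairs in the IBRD9, JQ1 and dBRD9 tables of CSS medium. The cause was not tested.

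A compound's effect differed between regular and CSS medium, by edgeR's test of the difference, for 10 genes with dBRD9, 285 with IBRD9 and 705 with JQ1. Of these 21 with IBRD9 and 54 with JQ1 went in opposite directions. For JQ1 the dose in CSS medium is not given, so medium and dose cannot be told apart. Enzalutamide moved KLK3 and KLK2 in opposite directions in the media: in the authors' deposited tables KLK3 was at 1.27 in CSS medium and -4.24 in regular medium, and KLK2 at 1.39 and -5.23, and the difference was not tested. Between the knockdowns 149 genes with non-overlapping groups went in opposite directions at 3 and 11 days, for example LRRC26 (-0.47 and 1.12), and this difference was not tested either. Chance separates 3 against 3 libraries for 10% of genes.

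Genes with CTATTCA in their 3' UTRs were lower more often than others in both knockdowns, though most lower genes lack the word. An shRNA seed match in 3' UTRs (off-target) would put the same word first in both knockdowns and not with a compound, and the word with the lowest score at day 3 had rank 1 at day 11 and rank 4978 with 5 µM IBRD9, and it occurs in 9 of 19 BRD9 transcripts. An effect of the shRNA on such transcripts may therefore be part of the knockdown's lower genes, as a hypothesis, since the shRNA sequence is not given in the sources used here and a label field names CRISPR-Cas9 for the day 11 cells. Of called genes with an annotated 3' UTR 7767 at day 11 and 3438 at day 3 lack the word, and overlapping words such as ACTATTC and TATTCAA also scored low, so both a wider seed effect and loss of BRD9 stay open for these genes.

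IBRD9 and JQ1 moved most of their shared genes the same way. Shared control libraries as the whole cause are argued against, since 5 µM IBRD9, with its own DMSO libraries, still had 89.1% of 5580 genes in the direction of JQ1 (exact 95% interval 88.3 to 89.9). Inhibition of BET bromodomains by micromolar IBRD9 may be a cause: among 4753 genes called with both compounds and in neither dBRD9 table, 88.9% (88.0 to 89.8) moved the same way. The dBRD9 tables list fewer genes, so loss of BRD9 function as the cause stays open for these genes. A share this high was also not particular to a BET inhibitor. Genes shared by 5 µM IBRD9 with enzalutamide and with CSS medium went the same way for 86.9% and 87.8%. With the day 3 and day 11 knockdowns the shares were 65.8% and 62.6%. The share with JQ1 therefore cannot tell BET inhibition from a response common to several treatments.

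KLK3 and KLK2 rose with enzalutamide in CSS medium. RNA of DMSO cells in regular medium mixed into those libraries would need equal shares for both genes, and the shares were 2.72% and 1.36%, a ratio of 1.996, between the limits set for and against it, so it cannot be told apart from a change in the cells. That verdict covers KLK3 and KLK2 alone and depended on which genes were included, a choice made after the result was seen. RNA of enzalutamide cells in regular medium cannot be told apart either, because its test had nothing to count. That test took genes listed in both tables, called by edgeR as differing and with a mean of at least 100 counts. Among these, 0 other genes differed as much as KLK2 between enzalutamide in regular medium and DMSO in CSS medium. The shares such mixing would need were 78.0% for KLK3 and 72.5% for KLK2 on a scale joined across tables, and they were computed for no other gene. A weak androgen-like action of enzalutamide at low androgen may be a biological explanation, and it was not tested.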

How the results depend on the processing

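Settings chosen after seeing the data were the counts without genes holding the 3' UTR word, the number of lists with an estimated correlation, the scaling of differences with TMM, the adjusted p of 0.01 for differences and the added overlaps. No named gene, list or overlap changed direction past its threshold in the alternatives run, but some balances of higher and lower genes turned over. Except at day 11, refits used genes already called from the same libraries, so a change of direction was unlikely there. Of the alternative results for named genes 8171 stayed on the same side of the threshold and 516 lost their call. For lists 380 stayed, 26 lost it and 4 gained it. At a mean of at least 100 counts JQ1 had 3921 higher and 3605 lower genes in regular medium and 2452 and 2044 in CSS medium, and the day 11 knockdown 4077 and 3919. At a log2 change of at least 1, 5 µM IBRD9 had 626 higher and 485 lower. Without the word genes the knockdowns had 4629 and 4525 at day 11 and 1932 and 1871 at day 3. With TMM the differing genes higher and lower with the first of each pair became 1451 and 1425 for IBRD9 against JQ1, 137 and 125 for enzalutamide against dBRD9 and 48 and 103 for enzalutamide against CSS medium, from 1374 and 1504, 110.0 and 165, and 76 and 66, and for dBRD9 against JQ1 in CSS medium 190.0 and 236, from 237 and 106; the cause was not tested. At an absolute log2 change of at least 1 the changed genes numbered 1111 with 5 µM IBRD9 for 3 days, 576 with enzalutamide, 926 with IBRD9, 3601 with JQ1 and 252 with dBRD9 in regular medium, 988 in CSS against regular medium, 594 with IBRD9, 2939 with JQ1 and 187 with dBRD9 in CSS medium, and 3116 and 427 in the day 11 and day 3 knockdowns, since this removes genes by construction. Lists past the threshold at that setting numbered 3, 2, 2, 3, 0 and 2 for the first 6 of these, and 0 for IBRD9 and 0 for dBRD9 in CSS medium and 0 for the day 3 knockdown. With genes at an adjusted p under 0.01 the lists fell from 6 to 4 for the day 3 knockdown, from 8 to 6 for enzalutamide in regular medium and from 7 to 6 for CSS against regular medium; with a mean of at least 100 counts they went from 7 to 6 for CSS against regular medium, and for JQ1 from 7 to 8 in regular and from 4 to 5 in CSS medium. At an adjusted p under 0.01 there were 613 genes with dBRD9 in regular medium, and 1236 with IBRD9 and 442 with dBRD9 in CSS medium. An edgeR refit of the listed genes gave 1369 for IBRD9 in CSS medium, where the cause was not tested. With a replicate block IBRD9 in CSS medium had 401 genes and dBRD9 in CSS medium 82, and the difference between enzalutamide and CSS medium 261 genes; residuals of libraries with the same number correlated between -0.633 and 0.602 over 11 comparisons, and in 0 were all over 0.1, so the numbers do not pair the samples. Leaving out each library in turn gave 7107 to 7383 genes for 5 µM IBRD9, 2836 to 3289 for enzalutamide, 4601 to 5038 for IBRD9, 9555 to 9670 for JQ1 and 518 to 914 for dBRD9 in regular medium, 2143 to 3698 for CSS against regular medium, 451 to 1916 for IBRD9, 4577 to 5891 for JQ1 and 106 to 675 for dBRD9 in CSS medium, and 9433 to 10274 and 3714 to 4203 at days 11 and 3. The libraries that moved a count over 1.5 times were DMSO 1, 2 and 3 in regular medium (518, 575, 533) and dBRD9 3 (560) for dBRD9, the same DMSO libraries (2182, 2204, 2226) and CSS DMSO 1 (2143) for the media, CSS DMSO 1 (499) and IBRD9 1, 2 and 3 (451, 614, 528) for IBRD9 in CSS medium, and CSS DMSO 1 (123) and dBRD9 1, 2 and 3 (106, 145, 110.0) for dBRD9 in CSS medium. Fewer samples and, except at day 11, a list of called genes alone went into these fits. Shares of genes in the same direction, in percent, were at an adjusted p under 0.01 97.2 for both knockdowns, 67.9 and 64.7 for the day 3 and day 11 knockdown with 5 µM IBRD9, 81.0 for enzalutamide, 96.6 for IBRD9 and 91.1 for dBRD9 with JQ1 in regular medium, 99.2 for IBRD9 and 86.1 for dBRD9 with JQ1 in CSS medium, 99.4 for IBRD9 and 99.4 for JQ1 between media, 99.9 for enzalutamide with CSS medium, and 78.4 and 88.3 for enzalutamide with the day 3 knockdown and 5 µM IBRD9. At a log2 change of at least 1 they were 99.3 for both knockdowns, 78.6 for the day 3 knockdown with 5 µM IBRD9, 97.4 for dBRD9 with IBRD9, 93.8 and 94.5 for enzalutamide with dBRD9 and IBRD9, 83.7, 99.4 and 95.1 for enzalutamide, IBRD9 and dBRD9 with JQ1, 96.9, 99.5 and 91.9 in CSS medium for dBRD9 with IBRD9, IBRD9 with JQ1 and dBRD9 with JQ1, 100 for IBRD9 and 100 for JQ1 between media, 100 and 88.9 for enzalutamide and dBRD9 with CSS medium, and 85.7 and 88.4 for enzalutamide with the day 3 knockdown and 5 µM IBRD9. With a mean of at least 100 counts JQ1 between media had 98.6. At an adjusted p under 0.01 the differences numbered 40 for enzalutamide with CSS medium, and 4, 180 and 413 between media for dBRD9, IBRD9 and JQ1. At day 11 DESeq2 called 9411 genes, a replicate block 9767 and no low-count filter 10470. Not run for the 11 tables of called genes, which lack the other genes, were TMM against DESeq2 size factors, no low-count filter and a joint fit of all groups of a medium. Also not run were refits for enzalutamide in CSS medium, with 4 genes, and set tests at a 2-fold change at day 11. Depth limits are unknown for these tables, since their full library totals are not known here.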

Other observations

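The splits of the 6 day 11 libraries were chosen after the results were seen, and the other values here were planned. For the day 11 knockdown, 1 of the 10 splits of the libraries gave 10056 or more genes with edgeR, the real one, and the highest other split gave 0. With 10 splits the share is too large to go under 0.05.

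Of the 22 gene lists 11 passed in at least 1 comparison, and 10 that could be tested passed the threshold in no comparison, among them BAF complex subunits, BET proteins and P-TEFb, basal, luminal, mesenchymal and neuroendocrine markers, hypoxia, immediate early genes and interferon-stimulated genes. The immune markers, never tested, had 0 called members in every comparison. In the authors' deposited tables VIM was at 2.47 with 5 µM IBRD9 and at 2.94 with JQ1 in regular medium, JUN at 2.40 and 2.56 with JQ1 in regular and CSS medium, SYP at 2.65 with JQ1 in regular medium, and ETV1 at -2.87 there. At day 11 of the knockdown, in the edgeR test, FN1 was at -3.04, OAS3 at -3.05, ETV1 at -3.14 and the BAF subunit gene SS18 at 1.32.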
